A study of Mus musculus with 9 samples.

How the data were processed

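Poly(A) RNA from mouse liver was measured by sequencing in 9 libraries of 3 groups, with 3 libraries per group. Per the labels' protocols, RNA was extracted with TRIZOL from a piece of whole liver and libraries were prepared with the Tecan universal plus mRNA-seq kit. The labels do not state whether counting used strand. Per the submitters' processing notes, HISAT2, Subread and DESeq2 were used with builds named mm39 and GRCm39, without versions.

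The deposit holds 2 tables of 28956 gene symbols by 9 columns. Per the file headers and values, 1 table holds raw read counts deposited as whole numbers. The other holds normalized counts, a per-library scaled signal that the authors deposited. Dividing the raw by the deposited normalized counts gave 1 factor per library, equal to the median-of-ratios size factor within 0.07%, so these are counts over DESeq2-type size factors. The column headers give the group of each library but no replicate number. Library numbers 1 to 3 therefore follow the column order within a group and cannot be matched to the numbers in the sample titles. No symbol was matched to coordinates. There were 24 extra symbol entries repeating another, and 22 symbols had been turned into dates, as spreadsheet software does. These entries stayed in the fit under their own names and none is named here.

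Depth was 53267000 to 63176000 counts per library, rounded to 5 digits. A count of 0 allows up to 3 counts, or 0.0475 to 0.0563 CPM, for counting error only. The 10 most abundant genes held 18.4% to 21.0% of counts and mitochondrially encoded genes 6.20% to 7.24%. Between libraries of a group, the median over genes of the chi-square of the counts, with library size allowed for, was 2.89 to 7.11, so the spread exceeded sampling noise. The median SD of log2 CPM within a group was 0.230 in APAP, 0.176 in APAP_MSC and 0.218 in APAP_HDF. Xist lay between 0.0905 and 0.491 CPM and Ddx3y between 49.2 and 61.6 CPM in all 9 libraries, so no library differed in sex.

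From the raw counts, differences were computed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the group, which left 17582 genes holding 99.966% of counts. TMM factors were 0.934 to 1.11 and the common biological coefficient of variation 0.197. A quasi-likelihood model with robust moderation was fitted to all 9 libraries with the group as its only term, so that the groups share 1 estimate of the spread. The comparisons were APAP_MSC with APAP, APAP_HDF with APAP, APAP_MSC with APAP_HDF, and a test of both group terms together. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05, two-sided. Printed levels are CPM with TMM-scaled library sizes as mean and SD, and fold changes are log2 with the SE from the fit.

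Gene lists fixed before the data were examined covered hepatocyte functions, stress and inflammatory responses, and markers of the other cell types of liver and blood. Of 44 lists, 43 had at least 5 tested members and were tested with camera of limma 3.58.1 at its preset correlation of 0.01, adjusted over the lists of a comparison. The remaining list had too few expressed members. Of 877 symbols in the lists, 861 were matched. Beside each list stand the number of members past the test over all genes and the number adjusted over the list alone. List levels per library are means over members of log2 CPM, with a prior count of 2, minus each gene's mean over the 9 libraries.

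The genes named were taken by a rule fixed before the data were examined. From each comparison it takes the 8 largest increases and the 8 largest decreases among genes past the test with a mean of at least 5 CPM, an ordinary symbol and no overlap between the groups. Where fewer than 4 genes pass in all, it takes the 4 with the smallest p. It adds up to 4 members of each list with the smallest p, and 19 fixed readouts in every comparison. Some genes that the rule takes are not reported here. Members of 2 later target gene lists named among the other observations lie outside the rule and were chosen after their values were seen.

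For the relation between the comparisons that share the APAP libraries, unchanged groups were simulated 50 times from the fitted means and dispersions with seed 1. For the share of genes with the same sign, 20 further simulations kept the APAP_MSC effects and left APAP_HDF unchanged, calling genes anew in each. The same steps were tested on simulated data in which a seeded set of genes had been changed by known amounts. Genes were drawn independently from means and dispersions common to the groups, with few genes per size, so differences between the comparisons can come from the draw. In the comparison of APAP_MSC with APAP, over 17240 genes, the test recovered 4.08%, 44.9%, 80.4% and 89.8% of genes changed by log2 0.5, 1, 2 and 3, with 10 false calls among 115. In APAP_HDF with APAP, over 17206 genes, it recovered 6%, 72.0%, 79.2% and 95.9%, with 5 false calls among 129. In APAP_MSC with APAP_HDF, over 17216 genes, it recovered 16.3%, 57.1%, 90% and 92%, with 9 false calls among 136.

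Alternatives were median-of-ratios factors in place of TMM, no low-count filter, a filter of at least 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, no robust moderation and the earlier quasi-likelihood method. Further ones were limma on log2 of the deposited normalized counts plus a pseudocount of 1, only the 2 groups compared in the fit, a minimum log2 fold change of 1, and leaving out each library in turn. For lists they were an estimated correlation and fry. Corrections for transcript GC content and length were added after the data were seen. They took these properties from an annotation of another build (GENCODE M21 on GRCm38), matched by symbol for 98.334% of tested genes, and no coordinates were used. Left out were fits by replicate number and by the number series in the sample descriptions, since the columns cannot be matched to either.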

Results

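RNA from mouse liver was sequenced in 9 libraries that the labels place in 3 groups of 3, named APAP, APAP_MSC and APAP_HDF. APAP, commonly short for acetaminophen, is a painkiller that injures hepatocytes at high dose. It was given intraperitoneally at 300 mg/kg to C57BL6J mice aged 8 weeks. In 2 groups, 500000 MSC or HDF cells per mouse were injected intravenously 90 min after APAP, and the series title gives 24 h as the time point. The labels do not expand MSC and HDF, which commonly stand for mesenchymal stromal cells and human dermal fibroblasts. The labels name hepatocytes as the cell type but a piece of whole liver as the material, so the values are read here as whole liver, and marker genes of other liver cell types were tested as lists. No untreated liver was sequenced. The labels state n = 3 but not that each library came from a separate animal, so the p-values measure the spread between these samples.

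Rounded to 5 digits, the total counts were 53267000, 54547000 and 63176000 in the APAP libraries, 58038000, 56612000 and 58131000 in the APAP_MSC libraries, and 57252000, 61582000 and 56174000 in the APAP_HDF libraries. A gene with 0 counts in a library could still lie at up to 3 counts, which is 0.0475 to 0.0563 CPM (counts scaled to a common library total) depending on the library. That floor covers counting error only. On the first principal component, which held 32% of the variance, the APAP_MSC libraries lay between 41 and 52.4 and the other 6 libraries between -43.1 and -11.3.

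The comparison of APAP_MSC with APAP asks how the liver transcriptome after APAP differed when MSC were given. Genes of fat synthesis, drug metabolism, bile acid synthesis and amino acid breakdown were higher in APAP_MSC, with the counts and tests of each list given next. Scd1, which encodes the enzyme that desaturates stearate, had 4159 ± 1498 CPM (SD, n = 3) in APAP_MSC against 333 ± 6.68 CPM in APAP, a 12.5-fold difference (log2 fold change 3.64 ± 0.30 SE, edgeR adjusted p = 7.69e-04). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, rose 8.29-fold, from 2.61 ± 1.26 to 21.4 ± 1.40 CPM (adjusted p = 0.0034). Car3, a muscle and liver carbonic anhydrase, rose 14.9-fold, from 47.4 ± 17.2 to 705 ± 122 CPM (adjusted p = 0.00465). Hamp, which encodes the iron hormone hepcidin, fell from 986 ± 223 to 183 ± 19.0 CPM (log2 fold change -2.43 ± 0.19, adjusted p = 4.03e-04).

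In the fatty acid synthesis list, 7 of 20 tested members rose and 0 fell, and 12 rose when adjusted over the list alone (camera adjusted p = 1.04e-15, adjusted p = 0.233 with an estimated correlation). Besides Scd1 they included Elovl3, an elongase of long fatty acids (log2 fold change 4.36 ± 0.72, adjusted p = 0.0175), Thrsp (2.74 ± 0.45, adjusted p = 0.0175) and the carbohydrate-responsive factor Mlxipl (1.13 ± 0.15, adjusted p = 0.00412). Of 23 phase I drug metabolism genes, 6 rose and 0 fell, and 13 rose when adjusted over the list alone (camera adjusted p = 3.78e-12, adjusted p = 0.238 with an estimated correlation). The cytochromes P450 Cyp2c50 (2.25 ± 0.35, adjusted p = 0.014), Cyp3a11 (1.65 ± 0.24, adjusted p = 0.00694) and Cyp2c70 (1.25 ± 0.18, adjusted p = 0.00566) were among them. Cyp2e1 and Cyp1a2, which are among the enzymes that convert APAP to its reactive metabolite, did not pass, with log2 fold changes of 0.67 ± 0.31 (adjusted p = 0.231) and 2.68 ± 0.70 (adjusted p = 0.0602). Of 27 phase II conjugation genes, 8 rose and 0 fell, and 13 rose when adjusted over the list alone (camera adjusted p = 9.53e-09, adjusted p = 0.238 with an estimated correlation). Examples were the glutathione transferase Gstm3 (2.14 ± 0.32, adjusted p = 0.0128) and the glucuronosyltransferase Ugt2b1 (1.22 ± 0.18, adjusted p = 0.00587).

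Of 21 bile acid synthesis and transport genes, 5 rose and 0 fell, while 8 rose and 1 fell when adjusted over the list alone (camera adjusted p = 8.60e-07, adjusted p = 0.238 with an estimated correlation). Besides Cyp7a1 they included Cyp27a1 (log2 fold change 0.85 ± 0.12, adjusted p = 0.00515), which opens the other route of bile acid synthesis, and Cyp8b1 (2.05 ± 0.48, adjusted p = 0.0443). In the urea cycle and amino acid catabolism list, 9 of 26 rose and 0 fell, and 12 rose when adjusted over the list alone (camera adjusted p = 5.21e-09, adjusted p = 0.405 with an estimated correlation). Hgd, of tyrosine breakdown, had a log2 fold change of 1.37 ± 0.26 (adjusted p = 0.0197). Of 22 glucose metabolism genes, 4 rose and 2 fell, while 5 rose and 3 fell when adjusted over the list alone, and the list did not pass as a set (camera adjusted p = 0.368). The fructose kinase gene Khk (1.24 ± 0.15, adjusted p = 0.0034) rose, and the pyruvate kinase gene Pkm, low in mature hepatocytes, fell (-1.48 ± 0.13, adjusted p = 7.44e-04). Of 4 further genes with the largest increases, Hsd3b5 (3.68 ± 0.71, adjusted p = 0.0249) acts on steroids and Serpina6 (3.54 ± 0.42, adjusted p = 0.0045) encodes corticosteroid-binding globulin. Inmt (3.51 ± 0.34, adjusted p = 0.0034) is a methyltransferase, and Rgn (3.14 ± 0.64, adjusted p = 0.0292) encodes regucalcin. Albumin (Alb) transcripts, at 73850 ± 10322 CPM in APAP, differed by -0.02 ± 0.18 (adjusted p = 0.958). The pericentral hepatocyte list shares Cyp7a1, Cyp27a1, Cyp1a2, Cyp2e1, Cyp2c29 and Cyp2a5 with the lists above. It had 3 of 19 members higher and 0 lower, and 7 higher when adjusted over the list alone (median 0.67, camera adjusted p = 5.21e-09, adjusted p = 0.238 with an estimated correlation). The periportal list shares Cps1, Ass1, Hal, Sds, Gls2, Arg1 and Uroc1 with the urea cycle and amino acid list, and Pck1 and G6pc with the glucose list. It is thus not separate from them. The periportal list had 3 of 19 higher and 1 lower (median 0.35, camera adjusted p = 0.00549, adjusted p = 0.429 with an estimated correlation). It did not pass without APAP library 3 (camera adjusted p = 0.116).

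Markers of infiltrating myeloid cells and of sinusoidal endothelium were lower in APAP_MSC. Of 18 monocyte and macrophage markers, 9 fell and 0 rose, and 12 fell when adjusted over the list alone (camera adjusted p = 2.33e-12, adjusted p = 0.238 with an estimated correlation). They included Chil3 (log2 fold change -2.34 ± 0.21, adjusted p = 7.69e-04), Cd68 (-1.25 ± 0.16, adjusted p = 0.00415) and Trem2 (-1.48 ± 0.23, adjusted p = 0.00915). Of 12 neutrophil markers, 5 fell and 0 rose, and 9 fell when adjusted over the list alone (camera adjusted p = 5.59e-08, adjusted p = 0.238 with an estimated correlation). S100a8, an alarmin of neutrophils, went from 2.78 CPM in APAP to 0.570 CPM (-2.29 ± 0.41, adjusted p = 0.0147) and S100a9 from 2.49 to 0.718 CPM (-1.79 ± 0.40, adjusted p = 0.0269). Of 16 sinusoidal endothelial markers, 6 fell and 0 rose, and 12 fell when adjusted over the list alone (camera adjusted p = 1.60e-10, adjusted p = 0.238 with an estimated correlation). Lyve1 (-2.05 ± 0.39, adjusted p = 0.0205) and Mrc1 (-0.90 ± 0.15, adjusted p = 0.00991) were among them. Kupffer cell markers, of the resident macrophages, had 1 of 15 members lower and 0 higher, and 2 lower when adjusted over the list alone (camera adjusted p = 5.51e-04, adjusted p = 0.44 with an estimated correlation). Without APAP library 3 that list did not pass (camera adjusted p = 0.054).

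Matrix genes and markers of other cell types also lay lower. Of 26 extracellular matrix genes, 2 fell and 0 rose, over all genes and when adjusted over the list alone (median log2 fold change -0.70, camera adjusted p = 1.69e-05, adjusted p = 0.429 with an estimated correlation). Hepatic stellate cell markers had 3 of 15 members lower and 0 higher, and 4 lower when adjusted over the list alone (median -0.19, camera adjusted p = 0.0116, adjusted p = 0.44 with an estimated correlation). That list did not pass without APAP library 1 (camera adjusted p = 0.078), APAP library 2 (0.0605) or APAP_MSC library 3 (0.0884). Its median was -0.08 without APAP library 2, -0.38 without APAP library 3 and -0.31 without APAP_MSC library 2. Of 10 T and NK cell markers, 1 fell and 0 rose, and 3 fell when adjusted over the list alone (median -1.09, camera adjusted p = 0.0216, adjusted p = 0.44 with an estimated correlation). The list did not pass without APAP library 3 (median -0.45, camera adjusted p = 0.203) or APAP_MSC library 3 (0.203).

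Markers of 2 other cell types lay on the opposite side. Among 12 cholangiocyte markers, 0 changed over all genes and 5 rose when adjusted over the list alone (camera adjusted p = 0.00238, adjusted p = 0.238 with an estimated correlation). Krt19, a keratin of bile ducts, had a log2 fold change of 0.78 ± 0.25 (adjusted p = 0.083). Of 7 tested erythroid markers, 1 rose, Alas2 (0.90 ± 0.21, adjusted p = 0.0349), and 1 rose when adjusted over the list alone (camera adjusted p = 0.00267, adjusted p = 0.407 with an estimated correlation). Without APAP library 3 the erythroid list did not pass (camera adjusted p = 0.0571). The plot of gene list levels shows these marker lists per library beside the metabolic lists.

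**Figure D1:**
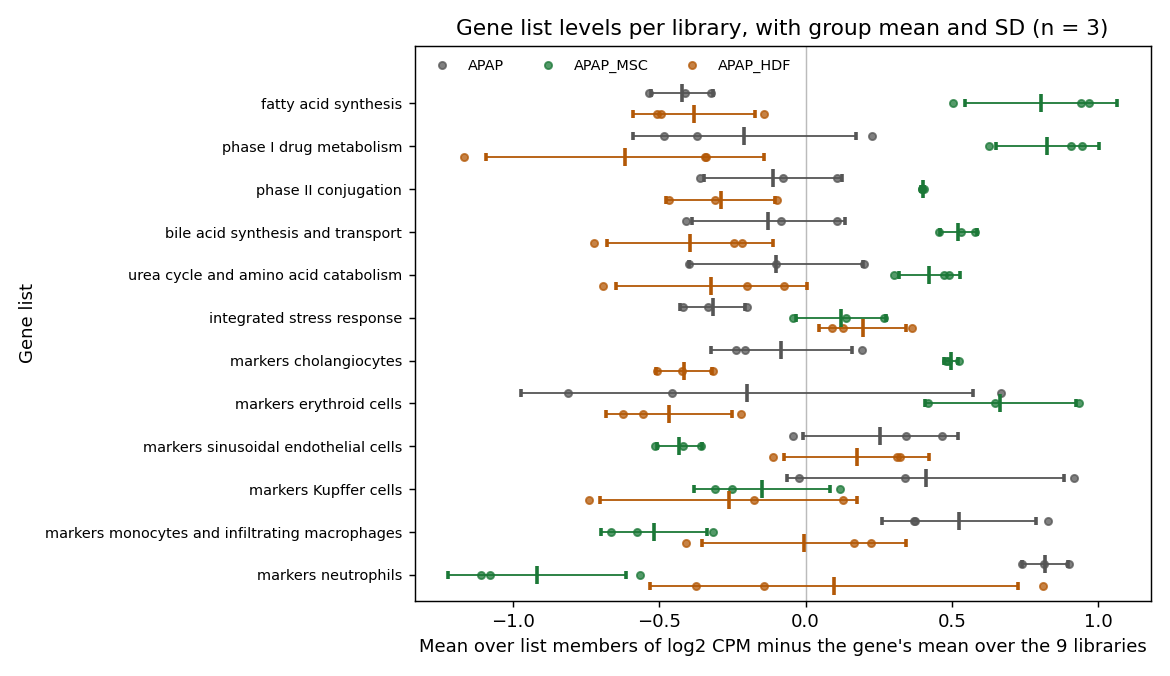
Level of 12 gene lists in each library (points), as the mean over list members of log2 CPM minus each gene's mean over the 9 libraries, with the group mean and SD (n = 3). The APAP_MSC libraries sit highest for the fatty acid synthesis, drug metabolism and bile acid lists and lowest for the sinusoidal endothelial and neutrophil markers, while the integrated stress response list lies higher in both cell-treated groups than in APAP.

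Immediate early genes were lower as well. Of 20 immediate early genes, 3 fell and 0 rose, and 5 fell when adjusted over the list alone (camera adjusted p = 3.72e-06, adjusted p = 0.405 with an estimated correlation). Klf6, which encodes a zinc finger transcription factor, had a log2 fold change of -1.46 ± 0.18 (adjusted p = 0.0034). Id1, a target of bone morphogenetic protein signalling, fell by 2.32 ± 0.18 on the log2 scale (adjusted p = 4.03e-04). The protease inhibitor gene Slpi (-2.83 ± 0.52, adjusted p = 0.0189), the scaffold gene Sh3pxd2b (-2.31 ± 0.42, adjusted p = 0.0186) and the annexin gene Anxa2 (-2.18 ± 0.43, adjusted p = 0.0271) fell. So did the vascular genes Angpt2 (-2.18 ± 0.36, adjusted p = 0.012) and Thbd (-2.18 ± 0.46, adjusted p = 0.0291). Of 31 acute phase genes, 5 fell and 0 rose, and 5 fell when adjusted over the list alone, but the list did not pass as a set (camera adjusted p = 0.138). The metallothioneins Mt1 (-1.27 ± 0.30, adjusted p = 0.0405) and Mt2 (-1.61 ± 0.31, adjusted p = 0.0205) and the endotoxin co-receptor Cd14 (-1.74 ± 0.34, adjusted p = 0.0216) were lower. The acute phase genes Saa1 (2.09 ± 1.11, adjusted p = 0.32) and Lcn2 (-0.35 ± 0.52, adjusted p = 0.752) did not pass. The cyclin-dependent kinase inhibitor gene Cdkn1a fell (-0.83 ± 0.16, adjusted p = 0.0173).

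NRF2 targets and glutathione genes, which respond to oxidative and electrophile stress, went both ways. Of 26 members, 2 rose and 5 fell, while 2 rose and 7 fell when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.299). The cystine transporter gene Slc7a11 (log2 fold change -1.10 ± 0.24, adjusted p = 0.0238) and Hmox1, of heme breakdown (-1.32 ± 0.33, adjusted p = 0.0498), fell. Me1 (0.68 ± 0.12, adjusted p = 0.0138) and Ephx1 (0.63 ± 0.13, adjusted p = 0.0216) rose. The glutathione synthesis genes Gclc (-0.42 ± 0.20, adjusted p = 0.236) and Gclm (0.18 ± 0.14, adjusted p = 0.506) and the quinone reductase gene Nqo1 (-0.70 ± 0.35, adjusted p = 0.283) did not pass. Among the remaining readouts fixed in advance, Il1b (-1.46 ± 0.43, adjusted p = 0.0678) and Ccl2 (-1.31 ± 0.44, adjusted p = 0.114), which draw in or are made by inflammatory cells, did not pass. Nor did Glul, Gdf15, Mki67 and Col1a1, whose adjusted p lay between 0.372 for Mki67 and 0.985 for Col1a1.

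**Figure D2:**
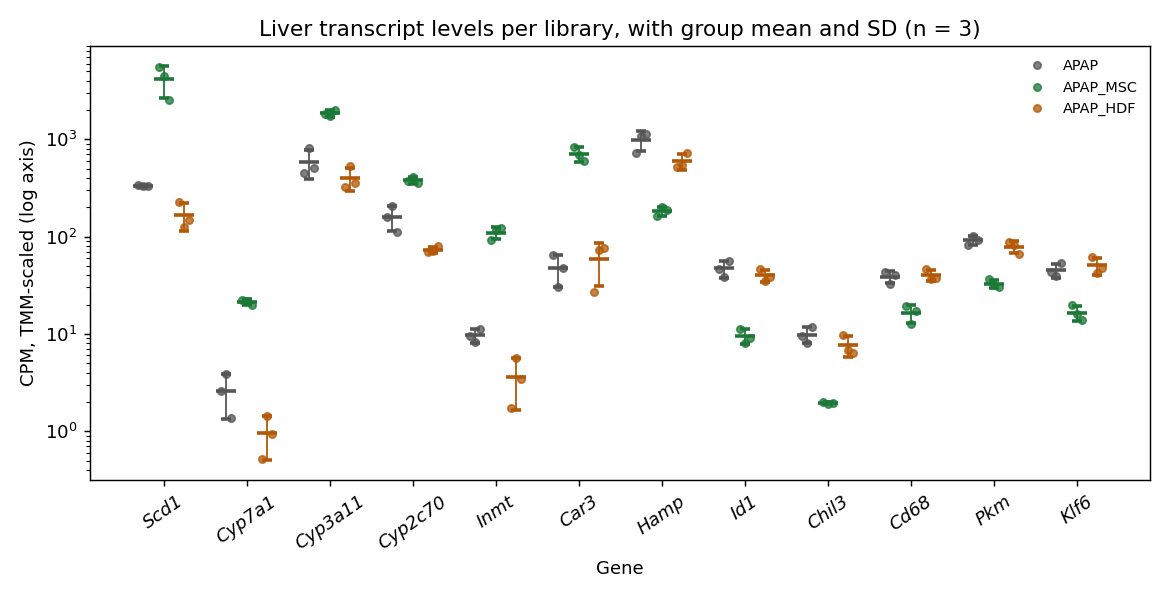
Transcript level of 12 genes in each library (points) on a log axis in CPM scaled by TMM factors, with the group mean and SD (n = 3). The APAP_MSC libraries lie above the APAP libraries for Scd1, Cyp7a1, Cyp3a11, Cyp2c70, Inmt and Car3 and below them for Hamp, Id1, Chil3, Cd68, Pkm and Klf6. For Scd1, Cyp2c70 and Inmt the APAP_HDF libraries lie below all 3 APAP libraries.

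In all, 1121 of 17582 tested genes differed between APAP_MSC and APAP (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted), 498 higher and 623 lower, of which 436 differed at least 2-fold. In 1120 of them the 3 libraries of one group all lay above the 3 of the other, an arrangement found for 28.5% of all tested genes and for 10% by chance. Of 43 gene lists tested with camera, 27 passed, 17 upwards and 10 downwards, and 0 passed with an estimated correlation, where the smallest adjusted p was 0.233. The count of 1121 depended on single libraries, being 97 without APAP_MSC library 2, 258 without APAP_MSC library 1, 380 without APAP_MSC library 3, 496 without APAP library 1, 698 without APAP library 2 and 1753 without APAP_HDF library 1. The calls of Car3, Cd68, Chil3, Cyp27a1, Cyp2c70, Cyp3a11, Cyp3a16, Cyp7a1, Gstm3, Hamp, Id1, Inmt, Itgb3, Khk, Klf6, Mlxipl, Nudt7, Nupr1, Pkm, Scd1, Serpina6 and Ugt2b1 held in each of these 9 fits, and those of the other 38 genes named as changed in this comparison, here or among the other observations, were lost in at least 1, with adjusted p up to 0.185. The Cyp8b1 call was lost in 8 of the 9 fits and those of Axl, Dock5, Npas2, Rgn and Slco1a1 in 7 each. Those of Alas2, Angptl4, Crim1, Fas, Hmox1, Mt1 and S100a9 were lost in 6 each. Reads of the Cyp2c, Cyp3a, Scd, Gstm, Ugt2b and Saa families can be shared between near-identical copies, and the use of strand was not stated, so single members are uncertain to that extent.

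The comparison of APAP_HDF with APAP asks how the liver after APAP differed when HDF were given. At the gene level 0 of 17582 genes passed the edgeR test, where the smallest adjusted p was 0.357 and 1544 genes had an unadjusted p under 0.05, while DESeq2 called 69 genes and limma-voom 0. The 1544 became 2509 without APAP_HDF library 1, 2418 without APAP library 3 and 875 without APAP_HDF library 3. Of the genes with the smallest p, 3 are given here, and none passed. Cyp2c70 had 73.0 ± 5.48 CPM (SD, n = 3) against 159 ± 46.3 CPM in APAP (log2 fold change -1.13 ± 0.18 SE, adjusted p = 0.438). Irx1, a homeobox gene, had 1.16 ± 0.466 against 0.222 ± 0.074 CPM (2.39 ± 0.40, adjusted p = 0.438). Dclk1 lay at 0.0491 CPM against 0.527 CPM in APAP (adjusted p = 0.357), with the lower value at the floor of 3 counts. Among the 19 readouts fixed in advance, log2 fold changes ran from -1.41 ± 0.40 for Cyp7a1 to 0.76 ± 0.36 for Gdf15, and the adjusted p from 0.482 for Glul to 0.973 for Saa1.

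By list, stress and fatty acid oxidation genes lay higher and matrix and macrophage genes lower in APAP_HDF, without any member passing over all genes. The matrix and macrophage lists lay lower in APAP_MSC as well, as given above, and the integrated stress response and heat shock lists lay higher there too. In APAP_MSC against APAP the heat shock list had 1 of 17 members higher and 0 lower, and 2 higher when adjusted over the list alone (median 0.30, camera adjusted p = 0.00287, adjusted p = 0.407 with an estimated correlation). That median was 0.18 without APAP library 1 and 0.53 without APAP library 3. In APAP_HDF against APAP the median log2 fold change of the integrated stress response list was 0.42, 0 of 21 members passed, and 6 were higher when adjusted over the list alone (camera adjusted p = 1.44e-09, adjusted p = 0.178 with an estimated correlation). Nupr1 had a log2 fold change of 1.20 ± 0.24 (adjusted p = 0.44) and Fgf21, a hormone the stressed liver secretes, 2.85 ± 0.63 (adjusted p = 0.463). In the heat shock list 0 of 17 members passed and 2 were higher when adjusted over the list alone (median 0.22, camera adjusted p = 3.88e-08, adjusted p = 0.443 with an estimated correlation). The HSP70 genes Hspa1a and Hspa1b were at 2.27 ± 0.45 (adjusted p = 0.44) and 2.20 ± 0.43 (adjusted p = 0.44). In the PPAR alpha and fatty acid oxidation list 28 of 30 members had a positive sign, 0 passed, and 0 passed when adjusted over the list alone (camera adjusted p = 1.44e-09, adjusted p = 0.637 with an estimated correlation). Acot2 was at 1.37 ± 0.37 (adjusted p = 0.493) and Pdk4 at 1.17 ± 0.38 (adjusted p = 0.523). In APAP_HDF against APAP the heat shock median was 0.43 without APAP library 3 and 0.34 without APAP_HDF library 3. The fatty acid oxidation median of 0.27 became 0.40 and 0.13 without the same libraries.

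In the extracellular matrix list 25 of 26 members had a negative sign, 0 passed, and 1 was lower when adjusted over the list alone (median -0.61, camera adjusted p = 1.86e-12, adjusted p = 0.637 with an estimated correlation). Col3a1, a fibrillar collagen gene, was at -1.14 ± 0.24 (adjusted p = 0.44). APAP_HDF library 3 stood apart, with a mean matrix level of -0.87 against 0.13 and 0.05 in the other APAP_HDF libraries and 0.44, 0.77 and 0.05 in APAP, and without it the median was -0.35. Between APAP_MSC and APAP_HDF the matrix list did not pass (camera adjusted p = 0.771). Hepatic stellate cell markers also passed downwards in APAP_HDF against APAP (median -0.34, and -0.17 without APAP library 2). That list did not pass without APAP library 1 (camera adjusted p = 0.0566) or APAP_HDF library 3 (0.0620). In the Kupffer cell list 14 of 15 had a negative sign, 0 passed, and 0 passed when adjusted over the list alone (median -0.73, camera adjusted p = 1.59e-08, adjusted p = 0.637 with an estimated correlation). Cd163, a scavenger receptor gene, was at -0.88 ± 0.29 (adjusted p = 0.523). The Kupffer level was highest in APAP library 3 (0.92) and lowest in APAP_HDF library 3 (-0.74), while the other APAP (-0.02 and 0.34) and APAP_HDF libraries (-0.18 and 0.13) overlapped. Monocyte and macrophage markers had a median of -0.65, with 0 of 18 passing and 0 when adjusted over the list alone (camera adjusted p = 4.89e-07, adjusted p = 0.637 with an estimated correlation). Without APAP library 3 the median was -0.42 for the Kupffer list and -0.37 for this one. The neutrophil list also passed downwards (median -0.57, and -1.21 without APAP_HDF library 1). The phase I drug metabolism list did too, with 0 of 23 members passing (median -0.31, camera adjusted p = 1.42e-05, adjusted p = 0.637 with an estimated correlation). It did not pass without APAP_HDF library 1 (camera adjusted p = 0.279), where its level was -1.17 against -0.34 and -0.34 in the other APAP_HDF libraries. In all, 18 of 43 lists passed with camera's preset correlation, 4 upwards and 14 downwards, and 0 with an estimated correlation, where the smallest adjusted p was 0.178. Without APAP library 3 the edgeR count was 32 and without APAP_HDF library 1 it was 1. On simulated counts for this comparison the test recovered 6% of genes changed by 0.5 on the log2 scale, 72.0% of those changed by 1 and 79.2% of those changed by 2. Each share rests on 48 to 50 genes of 1 draw. At a change of 1 the other comparisons gave 44.9% (APAP_MSC with APAP) and 57.1% (APAP_MSC with APAP_HDF) under the same settings. Genes were drawn independently and beside larger changes, so these shares do not give the power behind the 0 genes found here.

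The comparison of APAP_MSC with APAP_HDF asks whether the 2 cell types were followed by different liver transcriptomes, and it is the direct test of the difference between these groups. The numbers in the sample descriptions also put them in separate series, so a batch that follows those series cannot be told apart from the cell type. Drug metabolism, amino acid and lipid synthesis genes were higher after MSC. Inmt had 110 ± 16.4 CPM (SD, n = 3) in APAP_MSC and 3.65 ± 1.99 CPM in APAP_HDF (log2 fold change 4.92 ± 0.37 SE, edgeR adjusted p = 5.63e-04). Scd1 differed 24.9-fold (4.64 ± 0.32, adjusted p = 4.03e-04) and Cyp7a1 22.1-fold (4.46 ± 0.38, adjusted p = 5.63e-04). Serpina6 (4.10 ± 0.43, adjusted p = 0.00158), Cyp1a2 (3.65 ± 0.73, adjusted p = 0.0219), Rgn (3.63 ± 0.65, adjusted p = 0.0151), Car3 (3.59 ± 0.43, adjusted p = 0.003) and Cyp2c29 (3.56 ± 0.87, adjusted p = 0.0417) followed. Of the 9 fits that left out 1 library, the Cyp2c29 call was lost in 8, with adjusted p up to 0.121, the Cyp1a2 call in 5, up to 0.0917, and the Rgn call in 2, up to 0.0615.

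Of 23 phase I drug metabolism genes, 12 were higher after MSC and 0 lower, and 13 were higher when adjusted over the list alone (camera adjusted p = 2.65e-19, adjusted p = 0.245 with an estimated correlation). Cyp2c70 (log2 fold change 2.38 ± 0.19, adjusted p = 4.03e-04), Cyp2c50 (3.43 ± 0.37, adjusted p = 0.00185) and Cyp3a11 (2.19 ± 0.25, adjusted p = 0.00127) were among them. Phase II conjugation genes had 12 of 27 higher and 0 lower, and 14 higher when adjusted over the list alone (camera adjusted p = 1.51e-11, adjusted p = 0.245 with an estimated correlation). They included Papss2, which makes the sulfate donor (1.68 ± 0.16, adjusted p = 5.63e-04). In the urea cycle and amino acid list 14 of 26 were higher and 0 lower, and 15 higher when adjusted over the list alone (camera adjusted p = 1.77e-12, adjusted p = 0.412 with an estimated correlation). Otc was at 1.17 ± 0.20 (adjusted p = 0.00828) and Hgd at 1.55 ± 0.26 (adjusted p = 0.00878). The fatty acid synthesis list had 5 of 20 higher and 0 lower, and 11 higher when adjusted over the list alone (camera adjusted p = 1.75e-12, adjusted p = 0.245 with an estimated correlation). Thrsp was at 3.50 ± 0.47 (adjusted p = 0.00529) and Srebf1, a regulator of lipid synthesis, at 1.80 ± 0.27 (adjusted p = 0.0055).

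Of 21 bile acid genes, 6 were higher and 1 lower, and 10 higher and 1 lower when adjusted over the list alone (camera adjusted p = 1.89e-08, adjusted p = 0.278 with an estimated correlation). The bile salt export pump gene Abcb11 had a log2 fold change of 1.55 ± 0.24 (adjusted p = 0.00515) and Cyp27a1 of 1.07 ± 0.12 (adjusted p = 0.00107). Of 22 glucose metabolism genes, 5 were higher and 3 lower, and 7 higher and 5 lower when adjusted over the list alone (camera adjusted p = 0.0991). The glycogen phosphorylase gene Pygl (1.75 ± 0.15, adjusted p = 4.63e-04) and Khk (1.69 ± 0.15, adjusted p = 4.63e-04) were higher. Pkm (-1.26 ± 0.13, adjusted p = 7.03e-04) and the glucose transporter gene Slc2a1 (-0.77 ± 0.11, adjusted p = 0.00355) were lower. Cholangiocyte markers had 5 of 12 higher and 0 lower, and 9 higher and 1 lower when adjusted over the list alone (camera adjusted p = 9.73e-05, adjusted p = 0.245 with an estimated correlation). The chloride channel gene Cftr was at 0.476 CPM after MSC and 0.0706 CPM after HDF, close to the floor of 3 counts (2.69 ± 0.52, adjusted p = 0.0108), and Epcam differed by 1.12 ± 0.23 (adjusted p = 0.0142).

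Endothelial and immediate early genes were lower after MSC than after HDF. Of 16 sinusoidal endothelial markers, 6 were lower and 0 higher, and 12 lower when adjusted over the list alone (camera adjusted p = 8.82e-08, adjusted p = 0.412 with an estimated correlation). Lyve1 had a log2 fold change of -2.16 ± 0.39 (adjusted p = 0.0126) and Oit3 of -0.99 ± 0.15 (adjusted p = 0.00424). Of 20 immediate early genes, 4 were lower and 0 higher, and 9 lower when adjusted over the list alone (camera adjusted p = 5.01e-07, adjusted p = 0.412 with an estimated correlation). Klf6 was at -1.62 ± 0.18 (adjusted p = 0.00107) and Fosl1 at -2.04 ± 0.37 (adjusted p = 0.00912). The largest decreases also took in Angpt2 (-2.95 ± 0.36, adjusted p = 0.00166) and the transcription factor gene Runx1 (-2.51 ± 0.33, adjusted p = 0.00244). The protein C receptor gene Procr (-2.24 ± 0.21, adjusted p = 5.63e-04), Tnfrsf23 (-2.21 ± 0.43, adjusted p = 0.0151), Cd14 (-2.13 ± 0.35, adjusted p = 0.00753) and Sh3pxd2b (-2.13 ± 0.42, adjusted p = 0.0172) followed. Hamp fell by 1.70 ± 0.19 on the log2 scale (adjusted p = 0.00107). Monocyte and macrophage markers had 2 of 18 lower and 1 higher, and 4 lower and 1 higher when adjusted over the list alone (camera adjusted p = 6.60e-04, adjusted p = 0.432 with an estimated correlation). Chil3 (-1.98 ± 0.21, adjusted p = 0.001) and Cd68 (-1.30 ± 0.16, adjusted p = 0.00173) were lower and Spp1, osteopontin, was higher (0.91 ± 0.22, adjusted p = 0.0319). Kupffer cell markers had 0 of 15 members passing, and 0 when adjusted over the list alone (median 0.10, camera adjusted p = 0.824).

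Col3a1 was higher after MSC than after HDF (log2 fold change 1.25 ± 0.24, adjusted p = 0.0151). Of the readouts fixed in advance, Glul (0.57 ± 0.14, adjusted p = 0.0277) was higher. Gclc (-0.71 ± 0.20, adjusted p = 0.0477), Cdkn1a (-0.96 ± 0.16, adjusted p = 0.00577) and Mt1 (-1.16 ± 0.30, adjusted p = 0.0445) were lower, and Cyp1a2, Cyp3a11 and Cyp7a1 were higher as given above. The other 12 did not pass, with adjusted p from 0.0783 for Col1a1 to 0.862 for Alb.

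In all, 1563 of 17582 genes differed between APAP_MSC and APAP_HDF, 862 higher and 701 lower after MSC, and 513 of them at least 2-fold. In 1561 of them the groups did not overlap, which held for 33.2% of all tested genes against 10% by chance. Of 43 lists, 20 passed with camera, 15 upwards and 5 downwards, and 0 with an estimated correlation, where the smallest adjusted p was 0.245. The count was 361 without APAP_MSC library 2, 624 without APAP_MSC library 1, 939 without APAP_HDF library 2 and 984 without APAP_HDF library 1. Of 52 named calls of this comparison, 33 held in each fit that left out 1 library, among them Inmt, Scd1, Cyp7a1, Cyp2c70, Procr and Klf6, and 19 were lost in at least 1, with adjusted p up to 0.191. The lost calls were those of Cyp2c29 (in 8 of the 9 fits), Gclc, Mt1 and Spp1 (6 each), Cpt1a, Cyp1a2 and Cyp4a10 (5 each), and Glul and Sesn2 (4 each). Sh3pxd2b was lost in 3, Angptl4, Col3a1, Psat1, Rgn, Sdhb and Tnfrsf23 in 2 each, and Epcam, Fosl1 and Lyve1 in 1 each.

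Over the 3 groups together, 1230 genes differed in the edgeR test of both group terms. The count was 141 without APAP_MSC library 2, 324 without APAP_MSC library 1, 549 without APAP_MSC library 3 and 780 without APAP_HDF library 2. The 2 comparisons that involve APAP_MSC had 714 genes in common, all 714 in the same direction, 390 higher and 324 lower. These comparisons share the APAP_MSC libraries, so part of that overlap and of the shared direction comes from the shared samples, and how large a part was not tested. Across genes, the log2 fold changes of APAP_MSC and of APAP_HDF, each against APAP, had a Pearson r of 0.315 and a Spearman rho of 0.260, and genes are not independent replicates. Simulated unchanged groups that share the same controls gave r = 0.498 (0.475 to 0.517 over 50 simulations). The simulated groups had no changed genes, whereas APAP_MSC had 1121, which can lower r by itself. The 2 values of r are thus not a like comparison. The covariance was 0.0756 against a simulated 0.0603, a difference of 0.0153. Among the 1121 genes changed in APAP_MSC, 59.8% had the same sign in APAP_HDF, against 66.1% (64.5% to 68.3% over 20 simulations) for a simulated unchanged APAP_HDF group. Both kinds of simulation drew each gene independently, so their ranges leave out the correlation between genes and are too narrow for a test. The 3 APAP libraries cannot be split with 2 in each part, so part of any common value may come from the shared controls. The correlation was 0.440 without APAP library 3 and 0.218 without APAP_HDF library 3.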

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

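The tests of the share of other cell types, of blood, of fewer myeloid cells and of an equally large HDF response, the divisions of the APAP and APAP_HDF libraries, and the corrections for GC content and length, were chosen after the result they bear on was seen. The splits of the samples and the test of 1 deviating library were fixed before.

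The effects of MSC and of HDF, each against APAP, differed by the direct test in 1563 genes. In 142 tested genes the 3 APAP_MSC libraries lay above and the 3 APAP_HDF libraries below all 3 APAP libraries, and in 88 genes the reverse held, 230 in all. When the 6 APAP and APAP_HDF libraries were divided in each of the 20 possible ways, with APAP_MSC kept, the mean was 154 genes and the highest other division gave 469. In all, 5 of the 20 gave as many as the real one, so the number of such genes does not show opposite effects of MSC and HDF. Of these genes, 182 passed the direct test, but the order that selects them already separates APAP_MSC from APAP_HDF, so this adds nothing for opposite effects. Among the named genes this order was met, with log2 fold changes of APAP_MSC against APAP_HDF, by Inmt (4.92), Scd1 (4.64), Cyp2c50 (3.43), Cftr (2.69), Cyp2c70 (2.38), the clock output gene Dbp (1.95, SE 0.35, adjusted p = 0.00922), Pygl (1.75), Khk (1.69), Papss2 (1.68) and Abcb11 (1.55). Irx1 showed the reverse order (-3.22, SE 0.46, adjusted p = 0.00293). Between APAP_HDF and APAP the edgeR test called 0 genes, these included, while 1544 genes had an unadjusted p under 0.05, DESeq2 called 69 and limma-voom 0. Scd1 had a log2 fold change of -0.996 ± 0.277 there (adjusted p = 0.493).

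The broadest pattern is the set of 1121 genes that differed between APAP_MSC and APAP. Removing each library's trend over transcript GC content left 1144 genes and removing that over transcript length left 922, so neither trend was the whole cause. A smaller share of all cell types other than hepatocytes would lower the markers of each alike. The cholangiocyte level rose against the sinusoidal endothelial level by 1.27 (SE 0.29 over libraries, log2), but this difference contains the endothelial decrease itself. Cholangiocyte levels alone were -0.21, -0.24 and 0.19 in APAP and 0.48, 0.49 and 0.52 in APAP_MSC, though 0 of 12 markers passed over all genes. No fall was seen, which argues against a smaller share of all these cell types as the whole cause. A batch stays open: the numbers in the sample descriptions put all APAP_MSC samples in a series of their own, and all APAP_HDF samples in another with 1 of the 3 APAP samples, so series and group cannot be told apart for the 1121 genes or for the 1563 between APAP_MSC and APAP_HDF, and APAP_HDF against APAP was not checked for it because the columns cannot be matched to those samples. An effect of the MSC, the difference the design names, also stays open as untested against such a batch.

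The lower monocyte and neutrophil markers in APAP_MSC were weighed next. Less blood left in the tissue would lower red cell and neutrophil markers together. The erythroid level rose against the neutrophil level by 2.60 (SE 0.52, log2), but this difference contains the neutrophil decrease itself. Erythroid levels alone were -0.46, 0.67 and -0.81 in APAP and 0.65, 0.42 and 0.94 in APAP_MSC. The groups overlapped, so a rise is not settled, but no fall was seen, which argues against less blood as the whole cause. Fewer monocytes, macrophages and neutrophils, and lower expression per cell, stay open. A negative log2 fold change was found for 43 of 45 tested markers of these cells, 95.6%, but these markers make up the pattern itself, and in APAP_HDF against APAP 42 of the 45 were negative too, with 0 passing the edgeR test there, so the share decides nothing. The levels are small, with S100a8 at 2.78 CPM and S100a9 at 2.49 CPM in APAP.

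For the count of 0 genes between APAP_HDF and APAP (edgeR; 1544 with an unadjusted p under 0.05, DESeq2 69, limma-voom 0), a response as large as that to MSC which the test missed was weighed. Over the 1121 genes changed in APAP_MSC, the APAP_HDF log2 fold change, signed by the direction in APAP_MSC, had a median of 0.052 (quartiles -0.097 and 0.331) against a median size of 0.851 in APAP_MSC, while the median SE was 0.196 for APAP_HDF and 0.197 for APAP_MSC over all genes. This argues against an equal response in those genes, and it leaves open a response in other genes. Leaving out 1 of the 6 libraries gave at most 32 genes, without APAP library 3, which lay below the limit fixed before. Leaving out 1 of the 6 libraries of APAP_MSC against APAP still gave 97 genes (without APAP_MSC library 2) to 860 (without APAP library 3), a range that was not part of the rule fixed before. These counts argue against 1 deviating library hiding a response of the size seen with MSC. They do not address more than 1 deviating library. The count at an unadjusted p under 0.05 rose from 1544 to 2418 without APAP library 3 and to 2509 without APAP_HDF library 1, so a smaller response hidden by the spread of either stays open.

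Of the 100 drawn splits of the 9 libraries, out of 280 possible, 1 gave as many genes as the real groups, the real split itself with 1230. That share lies under 0.05 and is the smallest this draw can give. It holds only if the libraries are exchangeable, which a batch that follows the groups or a shared animal would break. The highest other split gave 770 genes and it, like the next with 653, kept the 3 APAP_MSC libraries together. The result thus bears on APAP_MSC against the other libraries more than on 3 separate groups. For the pairwise comparisons the 10 splits of 6 libraries are too few for a share under 0.05. There, 1 of the 10 splits reached the 1121 genes of APAP_MSC against APAP (highest other 5), 1 of the 10 reached the 1563 genes of APAP_MSC against APAP_HDF (highest other 0), and 10 of the 10 reached the 0 genes of APAP_HDF against APAP (highest other 1).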

How the results depend on the processing

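The corrections for GC content and length were added after the data were seen, and all other alternatives were fixed before. The edgeR counts stayed within 1.5 times of 1121, 1563 and 1230 under median-of-ratios factors, no filter, the stricter filter, limma-voom, no robust moderation, the earlier quasi-likelihood method, the deposited normalized counts with limma and both corrections, and, for the pairwise counts, with only the 2 groups in the fit. Those values ran from 882 (limma-voom) to 1413 (only the 2 groups) for APAP_MSC against APAP and from 1283 (length correction) to 1779 (only the 2 groups) for APAP_MSC against APAP_HDF. For the 3 groups they ran from 1001 (length correction) to 1250 (no robust moderation). The count for APAP_HDF against APAP was 0 under each of them. DESeq2 gave 1938, 69, 2349 and 2551 genes for APAP_MSC against APAP, APAP_HDF against APAP, APAP_MSC against APAP_HDF and the 3 groups, and the cause was not tested. A minimum 2-fold change left 436 and 513 genes for the APAP_MSC comparisons, by construction.

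Leaving out each library in turn gave 97 (without APAP_MSC library 2) to 1753 (without APAP_HDF library 1) genes for APAP_MSC against APAP and 0 to 32 (without APAP library 3) for APAP_HDF against APAP. It gave 361 (without APAP_MSC library 2) to 1793 (without APAP library 3) for APAP_MSC against APAP_HDF and 141 (without APAP_MSC library 2) to 1597 (without APAP_HDF library 1) for the 3 groups. Fewer samples lower the power of these fits. Why leaving out a library of a group outside the comparison moved a count was not tested. The filter kept 18011 genes without APAP_HDF library 1 and 18101 without APAP_MSC library 2, against 17582 in the main fit. A larger filtered set thus went with both the highest and the lowest count of APAP_MSC against APAP. Every one of the 97 genes left without APAP_MSC library 2 was among the 1121. Of 112 named calls, DESeq2 lost 0, limma-voom 6 and median-of-ratios factors 1, leaving out a library lost 57 in at least 1 fit, and none reversed under these settings.

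With an estimated correlation 0, 0 and 0 lists passed, against 27, 18 and 20 with the preset one, and with fry 12, 0 and 9, in the order APAP_MSC against APAP, APAP_HDF against APAP, APAP_MSC against APAP_HDF. The preset correlation of 0.01 lies far below most estimated ones, which widens that test. Without 1 library the list counts were 24 to 29, 17 to 21 and 20 to 24. The correlation across genes between the 2 comparisons against APAP was 0.218 (without APAP_HDF library 3) to 0.440 (without APAP library 3), and 0.428 without APAP library 2. For 5 list results the direction in camera turned when 1 library was left out. The medians over those fits were -0.53 to 0.28 for the interferon response and -0.39 to 0.26 for antigen presentation in APAP_MSC against APAP, and -0.68 to 0.10 for the interferon response in APAP_HDF against APAP, each turning without APAP library 3. They were -0.34 to 0.14 for cholesterol synthesis and -0.28 to -0.022 for the urea cycle and amino acid list in APAP_HDF against APAP, each turning without APAP_HDF library 1. The cause was not tested.

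No paired analysis was possible because the columns carry no replicate number. For the same reason the fits that use the number series of the sample descriptions were not run, including the one that keeps only the APAP sample in the series of the APAP_HDF samples. A count of 0 allows 0.0475 to 0.0563 CPM, so genes such as Dclk1 in APAP_HDF (0.0491 CPM) are limited by depth.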

Other observations

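Several further gene lists also differed between APAP_MSC and APAP, and some share members with those above. Genes with male-biased expression in liver had 5 of 19 members higher and 0 lower, and 9 higher when adjusted over the list alone (camera adjusted p = 5.82e-08, adjusted p = 0.238 with an estimated correlation). That list holds Elovl3 and Hsd3b5, named above, and shares Slco1a1 with the bile acid list. Its level was 0.89, 0.29 and 0.22 in the APAP_MSC libraries and -0.10, -0.23 and -0.54 in the APAP libraries. Nudt7, a peroxisomal hydrolase gene, had a log2 fold change of 2.27 ± 0.24 SE (edgeR adjusted p = 0.0034) and the organic anion carrier gene Slco1a1 of 2.05 ± 0.44 (adjusted p = 0.034). Genes with female-biased expression had 3 of 13 higher and 0 lower, and 4 higher when adjusted over the list alone (camera adjusted p = 0.00163, adjusted p = 0.407 with an estimated correlation). Cyp3a16 was at 2.31 ± 0.33 (adjusted p = 0.0056) and Cyp2c69 at 1.73 ± 0.32 (adjusted p = 0.0165). The lists of both sexes thus lay on the same side, and both Cyp genes belong to families with near-identical copies. Of 23 nuclear genes of oxidative phosphorylation, 0 passed over all genes and 10 were higher when adjusted over the list alone (median 0.27, camera adjusted p = 3.87e-07, adjusted p = 0.427 with an estimated correlation). After MSC compared with HDF, 4 of 23 were higher and 0 lower, and 18 higher when adjusted over the list alone (camera adjusted p = 7.30e-08, adjusted p = 0.43 with an estimated correlation). The succinate dehydrogenase gene Sdhb was at 0.60 ± 0.13 (adjusted p = 0.016).

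The integrated stress response list had 4 of 21 members higher and 0 lower in APAP_MSC than in APAP, and 8 higher when adjusted over the list alone (camera adjusted p = 2.17e-04, adjusted p = 0.238 with an estimated correlation). Nupr1 had a log2 fold change of 1.93 ± 0.24 (adjusted p = 0.00341) and Ddit3, which encodes CHOP, of 1.28 ± 0.23 (adjusted p = 0.0165). Between APAP_MSC and APAP_HDF that list had 1 member higher and 3 lower, and 3 higher and 4 lower when adjusted over the list alone (camera adjusted p = 0.824). Psat1 (-0.77 ± 0.16, adjusted p = 0.0168) and Sesn2 (-0.64 ± 0.14, adjusted p = 0.0215) were lower and Shmt2 (0.73 ± 0.14, adjusted p = 0.0101) was higher. Fatty acid oxidation genes had 1 of 30 higher and 3 lower after MSC than after HDF, and 3 higher and 7 lower when adjusted over the list alone (camera adjusted p = 0.0657). The lower ones were Angptl4 (-1.50 ± 0.31, adjusted p = 0.0202), Cyp4a10 (-0.96 ± 0.23, adjusted p = 0.0304) and Cpt1a (-0.82 ± 0.21, adjusted p = 0.0335). Of 22 p53 targets, 2 rose and 1 fell in APAP_MSC against APAP, both over all genes and when adjusted over the list alone (camera adjusted p = 0.368). The p53 targets Bbc3 (0.88 ± 0.18, adjusted p = 0.0198) and Fas (0.60 ± 0.15, adjusted p = 0.0443) rose and Cdkn1a fell. The list of cell death and damage sensing genes went down, with 3 of 23 lower and 0 higher, over all genes and when adjusted over the list alone, and 21 with a negative sign (median -0.17, camera adjusted p = 0.00198, adjusted p = 0.405 with an estimated correlation). That median was -0.25 without APAP library 1 and -0.10 without APAP library 3. Of 7 tested platelet markers, 1 rose and 1 fell, both over all genes and when adjusted over the list alone (camera adjusted p = 0.359). Gp9 went from 0.0652 CPM, close to the floor, to 0.422 CPM (2.72 ± 0.57, adjusted p = 0.0197) and Itgb3, which other cells also express, fell (-1.32 ± 0.20, adjusted p = 0.00673).

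The hypotheses that follow were formed from these data. The tests of feeding and of time of day were chosen after their results were seen and were redefined after a first version, that of time of day more than once, and the target gene tests were fixed before theirs were seen. The genes named from the target lists were chosen after their values were seen.

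Hamp and Id1, both lower in APAP_MSC, are known targets of bone morphogenetic protein signalling through SMAD proteins, and lower activity of that pathway may underlie both. Of 11 other tested targets, 1 was lower, Id2 (log2 fold change -0.83 ± 0.17, adjusted p = 0.0193), and 0 were higher, and their mean level shifted by -0.33 (SE 0.12 over libraries). The Id2 call was lost in 4 of the 9 fits that left out 1 library. The prediction asked for at least 2 lower targets, so these values leave the hypothesis open.

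Lower activity of the YAP and TEAD factors, which act in tissue repair, may underlie part of the decreases in APAP_MSC. Of 21 tested targets not seen before, 17 had a negative log2 fold change. Of the targets, 0 were higher and 3 were lower, Axl (-0.98 ± 0.24, adjusted p = 0.0391), Dock5 (-0.42 ± 0.10, adjusted p = 0.032) and Crim1 (-0.58 ± 0.15, adjusted p = 0.0404). Of the 9 fits that left out 1 library, the calls of Axl and Dock5 were lost in 7 each and that of Crim1 in 6. Their mean level shifted by -0.44 (SE 0.07 over libraries) in APAP_MSC and by -0.14 (SE 0.20) in APAP_HDF, each against APAP. The values go with the hypothesis as predicted, but a smaller share of endothelial or other cells that express these targets was not separated from it.

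The rise of lipid synthesis genes in APAP_MSC may reflect feeding, since liver switches these genes on after a meal. A first version of the test took genes of the fed state minus genes of the fasted state and gave a shift of 1.58 (SE 0.23), but it rests on the genes in which the pattern was seen. The version kept uses genes that fasting induces alone. Their mean level shifted by -0.14 (SE 0.09), and of 13 tested, 1 was lower, Angptl4 (log2 fold change -1.33 ± 0.31, adjusted p = 0.0379), and 0 were higher, which leaves feeding open. The Angptl4 call was lost in 6 of the 9 fits that left out 1 library. The fed genes shifted by 1.44 (SE 0.18), with 9 of 13 higher.

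A different time of day at sampling may also shift lipid genes. A first version of the test set clock genes that peak with Arntl against those that peak with Dbp, and the difference moved by 0.64 (SE 0.25) in APAP_MSC against APAP, which goes with the explanation. The genes that peak with Dbp were mixed there, with 5 of 9 negative (median log2 fold change -0.08). Dbp itself (0.76 ± 0.33, adjusted p = 0.19) and Nr1d1 (0.82 ± 0.28, adjusted p = 0.124) lay higher, neither past the test. In APAP_HDF against APAP the difference between the 2 sets of clock genes moved by 1.06 (SE 0.49), while the fed genes shifted by -0.13 (SE 0.16). There Npas2 was at a log2 fold change of 1.33 ± 0.41 (adjusted p = 0.504) and Dbp at -1.19 ± 0.36 (adjusted p = 0.504), neither past the test. A clock shift without a rise of the fed genes would speak against time of day as the whole cause, but the shift in APAP_HDF is little more than 2 SE. It ran from 0.637 (without APAP_HDF library 2) to 1.44 (without APAP_HDF library 1), and at its lowest it did not exceed the shift in APAP_MSC. Whether the clock moved at least as far there is thus not settled, and time of day stays open. Npas2 was higher in APAP_MSC (1.60 ± 0.41, adjusted p = 0.0469), and its call was lost in 7 of the 9 fits that left out 1 library.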
